A study of Mus musculus with 10 samples.

How the data were processed

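RNA sequencing was done on 10 mouse libraries, 3 from wild-type OPC cultures, 3 from Apc-deleted OPC cultures, 3 from cells sorted as cytotoxic macrophages and 1 from cells sorted as CD4-positive and labelled Th1. Per the labels' protocols, RNA was extracted with Trizol and sequenced on the Illumina HiSeq platform. Reads were placed on GRCm38 per the submitters' processing notes, while the aligner, the counting tool and their versions are not given in the sources used here. A note to the series says that raw files of 5 OPC samples were replaced, and it names none for wild-type replicate 2.

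For the OPC cultures the authors deposited a table of 1 comparison with 19333 genes. Per the file headers it holds the mean of normalized counts over the compared libraries, a log2 fold change with its standard error, a test statistic, a p-value and an adjusted p-value, under the column names of a DESeq2 results table. The tool behind the log2 fold changes made by the authors is not given in the sources used here. The statistic, a score with no fixed range, is the deposited log2 fold change divided by its standard error, as checked on the values. The p-values as deposited by the authors were used without change, except where a setting with fewer genes needed them adjusted again. The file names no numerator, so the sign was read from Notum, Sp5, Lef1 and Axin2 and turned to Apc-deleted over wild type. Each macrophage file holds, per the file headers, TPM (read counts corrected for transcript length and scaled to a common sum), read counts and normalized read counts computed by the authors. These are estimated counts, since between 79.8% and 80.26% of deposited values per macrophage library and 85.62% in the library labelled Th1 are exactly whole, with no tolerance, blanks left out and listed zeros included. The deposited normalized read counts equal the read counts times 1 factor per library, 1.014, 0.989 and 0.994, and that column is empty for the library labelled Th1. 5 columns were not used here, the FPKM column of each immune library and that empty column. The column codes of the macrophage files appear in no label, so these columns were assigned to the group and not to a replicate.

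OPC values come from the authors' table, since no value per library was at hand for a test. The design set before the data were examined had assumed values per library, with edgeR or limma for genes and camera for lists. With a comparison table, lists were tested instead with cameraPR of limma 3.58.1 on the statistic, at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 32 lists. A list needed 3 measured members, and members were also counted when adjusted over the list alone. An estimated correlation and fry need values per library and could not be run, so a correlation of 0.05, ranks, and fold changes in place of the statistic were tried. The 37 lists were fixed before the data were examined. Of 200 simulated lists of 20 genes, 98% had an unadjusted cameraPR p under 0.05 when the statistic was shifted by 1 and 4% when it was not. The simulated genes were independent, so these rates do not cover lists of genes that vary together.

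In the immune files blanks were taken as 0 and estimated counts were rounded to whole numbers. The library labelled Th1 was compared with the macrophage libraries by edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, Benjamini-Hochberg) at an adjusted p under 0.05 and at least 4-fold, with the spread taken from the macrophage libraries. On simulated counts for this comparison over 10241 genes, 50 of 50 genes raised 8-fold and 40 of 50 lowered 8-fold were recovered, against 2 of 50 raised 3-fold and 7 of 50 lowered 3-fold, with 1 false call among 10041 unchanged genes. In that simulation the single library had the mean profile and spread of the macrophage libraries, with most genes unchanged. Its rates therefore do not carry over to the library labelled Th1, whose profile lay far from theirs and whose own spread is unknown. A floor of 3 reads equals 0.983 CPM in the library labelled Th1 and between 0.127 and 0.13 in the macrophage libraries. Folds against libraries without a read were bounded at that floor, taken over the macrophage group or in the library labelled Th1, and the smallest bound over the 3 scalings is given. DESeq2 1.42.0 gave the alternative size factors and test. Gene names and coordinates come from GENCODE M21, where 99.81% of OPC identifiers matched, and a RefSeq table of GRCm38.p6, where 99.72% of immune identifiers matched. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

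Named genes followed a rule set before the data were examined. For OPCs these are Apc, the 10 largest called changes each way without predicted genes, and list members with the smallest p. The further condition that genotypes do not overlap could not be applied without values per library. For the immune libraries they are the 10 largest folds each way, the 10 most abundant genes and the leading list members. Genes named only as examples or beside a test in the closing section were chosen after their values were seen. Alternatives chosen after seeing the data are a mean of at least 50 normalized counts, removal of genes enriched in the macrophage libraries (at least 20 TPM and 10 times the OPC share), the 3 cameraPR settings and total-count scaling.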

Results

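RNA sequencing covered 10 mouse libraries from 4 groups. 6 libraries came from oligodendrocyte precursor cells (OPCs), the progenitors of myelinating oligodendrocytes, which had been purified on antibody-coated dishes (immunopanning) and grown for 3 days with the mitogen PDGFAA. 3 of these carried Olig2-Cre with floxed Apc alleles, so that Cre recombinase deletes Apc in Olig2-expressing cells, and 3 came from littermates with the floxed alleles alone, here called wild type. The remaining 4 libraries were sorted from spinal cords on day 18 of experimental autoimmune encephalomyelitis (EAE), a model of multiple sclerosis, in mice that combine Pdgfra-CreER with floxed Apc. 3 of them hold cells positive for CD11b, Gr-1 and NK1.1, named cytotoxic macrophages by the submitters, and 1 holds CD4-positive cells labelled Th1. The macrophage libraries summed to 23174908, 23564215 and 23474168 estimated reads, and the library labelled Th1 to 3051730. For the OPC cultures the authors' deposited table gives 1 comparison of 19333 genes with no value per library, so the depth of each OPC library is unknown and no spread or n of an own test stands beside its values. That table lists the neuronal genes Tubb3 and Nefl at means of 122300 and 61470 normalized counts, against 2251 for Pdgfra, so whether its values describe purified OPCs is open, and they are called OPC values after the labels. Coordinates below are on GRCm38. No source used here says that the macrophage libraries came from separate animals, so their p-values and SDs measure only the spread between these libraries, which may be technical.

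The first comparison asked which transcripts differ in OPCs without Apc, a scaffold of the complex that degrades beta-catenin and so restrains Wnt signalling. Apc itself (chromosome 18, 34220924 to 34322552) had a log2 fold change of -0.14 with an SE of 0.13 in the authors' deposited table, at an adjusted p of 1. A gene-level value does not isolate the floxed part of the transcript, so it checks neither the deletion nor the labels. The numerator of the fold changes is not stated in the authors' deposited table. Direction was therefore inferred from Notum, Sp5, Lef1 and Axin2, feedback targets that Wnt signalling induces, and every sign below is given as Apc-deleted over wild type on that reading. The direction of those targets is for this reason no independent evidence.

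With that reading, 76 genes rose and 30 fell in the Apc-deleted OPCs at an adjusted p under 0.05 in the authors' deposited table. At least 2-fold changes made up 63 of the increases and 9 of the decreases. An unadjusted p under 0.05 in the authors' deposited table was held by 701 genes, fewer than the 967 that chance alone would give among 19333, with a median p of 0.577 and an SD of the statistic of 0.944. The 10 largest increases among named genes in the authors' deposited table were those of Ccl4, Rgs1, Notum, Mmp12, Gpnmb, Ly9, Bcl2a1b, Lyz2, Cdh3 and Irf5. Ccl4, a chemokine that attracts leukocytes (chromosome 11, 83662584 to 83664683), rose 128-fold, with an SE of 1.35 on the log2 scale and an adjusted p of 0.000137 in the authors' deposited table. Its level there was low, at a mean of 22.1 normalized counts, and the fold and the mean in the authors' deposited table together imply 0.342 normalized counts in wild type, so the size of that fold is uncertain. Notum, a secreted enzyme that inactivates Wnt ligands (chromosome 11, 120653788 to 120661175), rose by 4.90 with an SE of 0.49 and an adjusted p of 2.31e-19 in the authors' deposited table. The macrophage-associated genes Mmp12, Gpnmb and Lyz2 rose by 4.76, 4.49 and 4.33 with SEs of 1.09, 1.05 and 0.96 in the authors' deposited table. These SEs are 4.03, 7.88 and 7.07 times those of genes of similar mean level, and that of Ccl4 3.12 times. The cadherin gene Cdh3 rose by 3.67 with an SE of 0.50. The other large increases in the authors' deposited table were 5.02 for Rgs1, 4.44 for Ly9, 4.37 for Bcl2a1b and 3.41 for Irf5, each from a mean under 20 normalized counts. Bcl2a1b belongs to a cluster of near-identical paralogs, so its reads may be shared with them.

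The 10 largest decreases among named genes were smaller than the increases. Dll3, a Notch ligand (chromosome 7, 28293553 to 28302238), changed by -1.48 with an SE of 0.16 and an adjusted p of 2.66e-15 in the authors' deposited table. Nkx2-2, a transcription factor that promotes oligodendrocyte differentiation, changed by -1.44 (SE 0.24), and Gpr17, a receptor of cells committed to differentiate, by -1.16 (SE 0.15) in the authors' deposited table. Enpp6, a choline phosphodiesterase of newly formed oligodendrocytes, changed by -1.15 (SE 0.25), and Myrf, the regulator of myelin genes, by -1.08 (SE 0.24) in the authors' deposited table. Elmo1, Neu4, Lims2, Sh3bp4 and Cd9 followed with log2 fold changes between -1.04 and -0.96 in the authors' deposited table.

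Among Wnt feedback targets, 19 of 21 measured genes pointed higher in the authors' deposited table and 8 passed an adjusted p of 0.05, while 10 passed when adjusted over the list alone. Beside Notum these were Rnf43 (2.89, SE 0.39), Nkd1 (2.47, SE 0.50), Sp5 (2.10, SE 0.33), Lef1 (1.89, SE 0.29), Tnfrsf19 (1.83, SE 0.27), Wif1 (1.51, SE 0.29) and Axin2 (1.01, SE 0.20) on the log2 scale of the authors' deposited table. As a set the list stood above the other genes with an adjusted p of 9.4e-41 by limma cameraPR on the statistics of the authors' deposited table. Its members Notum, Sp5, Lef1 and Axin2 set the sign, so the direction of the list is in part fixed by that reading. No test without them was run. The fixed list of Wnt pathway components did not move as a set (adjusted p = 0.143), and of 27 measured members 1 passed, Tcf7l2, a transcription factor that partners beta-catenin, at -0.43 (SE 0.12) in the authors' deposited table. Outside that list, and named after their values were seen, the ligand gene Wnt6 (1.57, SE 0.25) and the receptor gene Fzd10 (1.27, SE 0.27) rose in the authors' deposited table.

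Myelin and differentiation genes were lower as a set, with an adjusted p of 5.61e-13 by limma cameraPR on the authors' deposited table. Of 22 measured members 20 pointed lower, and 3 passed in the authors' deposited table, namely Enpp6, Myrf and Bcas1 (-0.65, SE 0.15). Adjusted over the list alone, 8 members fell and 1, Gjb1 (0.56, SE 0.24), rose. The abundant myelin gene Mbp was at -0.12 (SE 0.12) in the authors' deposited table and did not pass. OPC identity genes were split in the authors' deposited table, with Matn4, an extracellular matrix protein, 1.01 higher (SE 0.24) and Gpr17, Nkx2-2 and Neu4 lower, while Olig2 was at -0.03 (SE 0.25) and Pdgfra at 0.37 (SE 0.20). That list passed as a set in the lower direction by limma cameraPR (adjusted p = 0.00778). It lost its call at a preset correlation of 0.05 (adjusted p = 0.0508), with ranks (0.606) and with fold changes (0.312). In the authors' deposited table the BMP ligands parted, with Bmp7 at 0.94 (SE 0.25) and Bmp4 at -0.83 (SE 0.18), both past the threshold, and their list of BMP and Notch targets did not move as a set (adjusted p = 0.607).

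Cell cycle genes all pointed higher, 23 of 23 with a median log2 fold change of 0.70 in the authors' deposited table, but no member passed. The lowest unadjusted p in the list was 0.0132, for Ccne1. Their SEs in the authors' deposited table were a median of 4.35 times those of genes of similar mean level, from 1.26 times for Ccne1 to 5.82 times for Plk1. For most members this places a wide spread between libraries of one genotype beside the list. The set test gave an adjusted p of 1.01e-07 by limma cameraPR, with a preset correlation that takes no account of such shared spread.

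Of 14 measured chemokines 1 passed, Ccl4, and Ccl3 stood at 3.23 (SE 1.05) with an adjusted p of 0.239 in the authors' deposited table. Ccl9 (1.29, SE 0.58), Ccl6 (0.68, SE 0.37), Cxcl5 (1.08, SE 0.74), Cxcl12 (-0.08, SE 0.19) and Cxcl14 (0.01, SE 0.14) did not pass in the authors' deposited table. By limma cameraPR the chemokine list passed as a set (adjusted p = 0.0345). It lost its call at a correlation of 0.05 (adjusted p = 0.0999) and with ranks (0.453), and kept it with fold changes (9.31e-14). Among chemokine receptors in the authors' deposited table, Cxcr4 rose by 2.53 (SE 0.56) and the scavenger receptor Ackr3 by 1.91 (SE 0.41), and both bind CXCL12. That list had an adjusted p of 0.0169 by limma cameraPR, 0.0508 at a correlation of 0.05, 0.488 with ranks and 0.0355 with fold changes. Markers of phagocytes moved with Ccl4, since 13 of 15 measured macrophage and monocyte markers pointed higher in the authors' deposited table (set adjusted p = 1.48e-07) and Lyz2 and Cd68 (1.54, SE 0.36) passed. Within that list in the authors' deposited table Csf1r was at 0.01 (SE 0.16) and Mertk at 0.00 (SE 0.15). Microglia markers had a median of 0.01 over 10 genes in the authors' deposited table, with Sall1 at 0.85 (SE 0.26) and Tmem119 at 0.87 (SE 0.31) passing only when adjusted over the list alone, and the list did not pass as a set (adjusted p = 0.118). Neutrophil markers pointed lower for 10 of 11 genes with none past the threshold in the authors' deposited table (set adjusted p = 0.0473, and 0.113 at a correlation of 0.05). Of the sex-linked genes in the authors' deposited table, Xist was at 0.66 (SE 0.21, adjusted p = 0.175), Kdm5d at -0.39 (SE 0.20), Eif2s3y at -0.45 (SE 0.25), Uty at -0.40 (SE 0.23) and Ddx3y at -0.06 (SE 0.145), none past the threshold. Xist passed when adjusted over the list alone.

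Of the other lists, antigen presentation, immediate early and stress genes, and plasma cell markers were higher as sets with adjusted p of 0.00894, 0.0127 and 0.0345, and at a correlation of 0.05 with adjusted p of 0.0508, 0.0543 and 0.0543. By limma cameraPR with ranks the adjusted p were 0.0125, 0.0377 and 0.149, and with fold changes 0.0170, 0.305 and 0.0752. No member of these 3 lists passed on its own in the authors' deposited table, where B2m stood at 0.55 (SE 0.26) and Ier2 at 0.82 (SE 0.32). Erythroid genes (adjusted p = 0.000267), extracellular matrix genes (0.00589) and neuron markers (0.0473) were lower as sets, the last 2 with adjusted p of 0.0508 and 0.115 at a correlation of 0.05. In the same order, limma cameraPR gave adjusted p of 0.0302, 0.0456 and 0.0302 with ranks. With fold changes all lost their call, at 0.312, 0.344 and 0.523. The matrix genes Tnr (-0.57, SE 0.14) and Timp3 (-0.83, SE 0.22) fell in the authors' deposited table, whereas Hba-a1 at -0.39 (SE 0.11) did not pass. Sets that did not pass were interferon response, cholesterol synthesis, Schwann and neural crest, cytotoxic effectors, T cell, dendritic, astrocyte, NK, cytokine and growth factor, interferon gamma and Th1 axis, Th1, B cell, endothelial, pericyte and fibroblast, and sex-linked genes. Their adjusted p ran, in that order, 0.400, 0.400, 0.644, 0.644, 0.644, 0.400, 0.400, 0.400, 0.679, 0.400, 0.119, 0.880, 0.185, 0.342 and 0.255. The sex-linked list joins Xist to Y-linked genes, which a difference in sex would move in opposite directions, so its set test cannot show such a difference. The point values did lie in opposite directions, Xist higher and each measured Y-linked gene lower, with none past the threshold over all genes. Whether the sex make-up of the cultures differed between genotypes was not tested and stays open. Median, mean and test differed in sign for the cytotoxic effector, astrocyte, B cell and Schwann lists. Lists of CD4 lineage, CD8 lineage, Th2, Th17 and regulatory T cell genes had under 3 measured members and were not tested as sets. None of their members passed in the authors' deposited table, where Runx3 (1.49, SE 0.61) had the lowest unadjusted p among them.

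**Figure D1:**
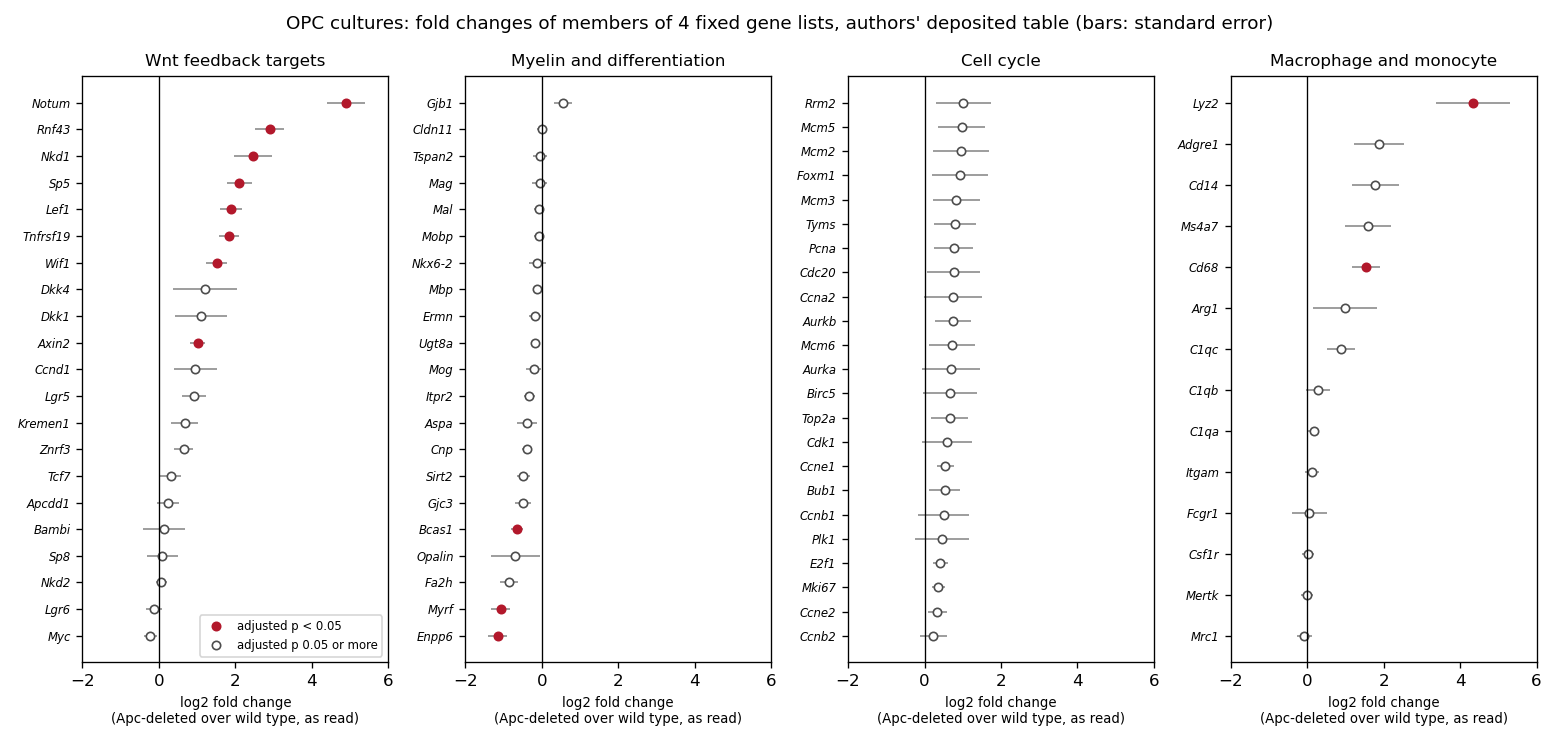
Log2 fold changes of members of 4 fixed gene lists in OPC cultures from the authors' deposited table, as Apc-deleted over wild type on the inferred sign (x axis), 1 gene per line, with bars for the SE and filled points for an adjusted p under 0.05. Wnt feedback targets reach 4.90 for Notum, all 23 cell cycle genes lie above 0 with wide bars and no filled point, and Lyz2 and Cd68 are the filled points among macrophage and monocyte markers.

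The second part described the 2 populations sorted from EAE spinal cord. The macrophage libraries were led by granulocyte and monocyte transcripts. The fixed neutrophil list, with S100a8 foremost, took 43.5% of their TPM and the fixed macrophage and monocyte list 3.44%. The name macrophage is therefore kept as a label only. S100a8, a subunit of the neutrophil protein calprotectin (chromosome 3, 90669071 to 90670034), reached 310396 ± 2006 TPM (SD, n = 3), and its partner S100a9 64978 ± 433 TPM. After S100a8, S100a9, Retnlg and Lyz2 the 10 most abundant genes were Tmsb4x, Tyrobp, Lcn2, Camp, Wfdc17 and S100a11, and these 10 took between 49.3% and 49.6% of TPM per library. All 14 neutrophil markers were at 1 TPM or more, among them Retnlg at 30979 ± 544, Lcn2 at 10331 ± 109, Camp at 10089 ± 102 and Ngp at 7188 ± 213 TPM (SD, n = 3). Of 17 macrophage and monocyte markers 14 reached 1 TPM, with Lyz2 at 22679 ± 122, Ly6c2 at 6376 ± 160, Plac8 at 4653 ± 18.7 and Cd68 at 207 ± 6.1 TPM (SD, n = 3).

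The genes behind the sorting antibodies had unequal levels. Ly6g and Ly6c2, which encode the Gr-1 antigens, stood at 743 ± 14.2 and 6376 ± 160 TPM, and Itgam, which encodes CD11b, at 12.3 ± 0.34 TPM (SD, n = 3). Klrb1c, which encodes NK1.1, was at 0.073 ± 0.025 TPM (SD, n = 3). Cytotoxic effectors were mostly low, with the perforin gene Prf1 at 0.080 ± 0.020, Gzmb at 0.34 ± 0.026, Gzma at 8.79 ± 0.31 and Nkg7 at 16.6 ± 0.41 TPM, against 775 ± 14.2 TPM for the granule proteoglycan Srgn (SD, n = 3). Of 13 NK cell markers 3 reached 1 TPM, the highest being Gzma. The most abundant chemokines were Cxcl2 at 685 ± 3.4, Ccl6 at 558 ± 6.6, Ccl2 at 174 ± 2.9, Ccl3 at 142 ± 1.4, Ccl5 at 123 ± 4.2 and Ccl4 at 118 ± 1.6 TPM (SD, n = 3). Among chemokine receptors Cxcr2 stood at 48.4 ± 0.69, Ccr2 at 29.7 ± 0.63 and Ccr1 at 28.2 ± 0.56 TPM (SD, n = 3). Globin genes were present, with Hba-a2 at 1475 ± 19.2 TPM (SD, n = 3), whereas T cell markers summed to 4.33 TPM and B cell markers to 6.39 TPM. These sums cover the 13 of 16 listed T cell genes and 6 of 8 listed B cell genes that the annotation holds, so they are incomplete.

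In the library labelled Th1 the transcripts of its label were largely without a value. Cd3e, Cd3d, Cd3g, Cd4, Tbx21 and Ifng had no read, where a count of 0 among 3051730 allows a level of up to 0.983 CPM by counting error alone, which is all that floors and intervals here cover. Of 13 measured T cell markers 1 exceeded 3 reads, the kinase gene Lck with 422 reads and 66.3 TPM. The annotation lacks the rest of the 16 listed T cell genes, so their levels are unknown. Of the 9 Th1 markers 1 exceeded 3 reads, the chemokine Ccl5 with 2863 reads and 2265 TPM, a gene that the macrophage libraries also express. Since the label rests on the sort alone and these values go against it, the name is kept as a label only. By contrast, 12 of 17 macrophage and monocyte markers exceeded 3 reads, including Lyz2 with 32518 reads (11006 TPM), Cd14 with 3597 reads (734 TPM), C1qb with 3017 reads (971 TPM) and Ms4a7 with 1444 reads (394 TPM). The most abundant genes there included Rpl32, Rps27, Rps19, Fth1, Rps23, S100a8, Ftl1, Rpl35 and Lyz2. Ribosomal protein genes have many processed pseudogenes, so their values are uncertain.

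**Figure D2:**
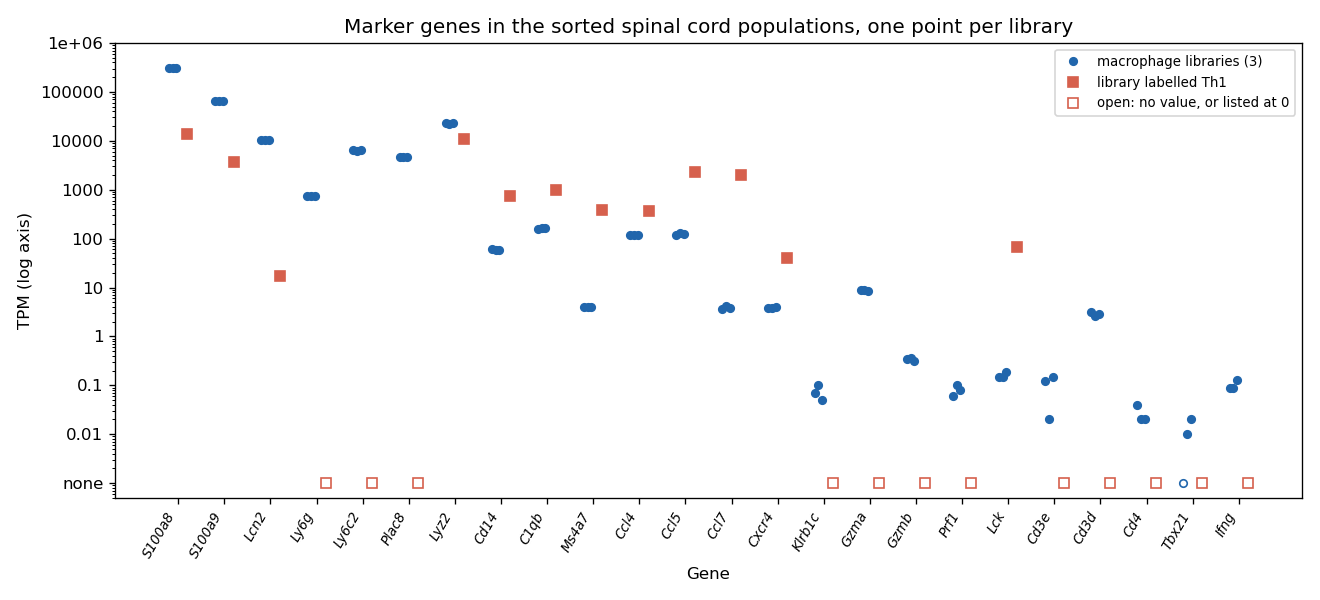
TPM of 24 marker genes (y axis, log scale) in the 3 macrophage libraries (circles) and the library labelled Th1 (squares), 1 point per library, with open symbols on the lowest line for genes without a read. The macrophage libraries lie close together, S100a8 reaches 310396 TPM on average, and Cd3e, Cd3d, Cd4, Tbx21 and Ifng have open squares.

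The third comparison set the library labelled Th1 against the macrophage libraries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7812 of 11447 genes differed at least 4-fold at an adjusted p under 0.05, 1567 higher and 6245 lower in the library labelled Th1, so that 20.06% of the calls were higher. That share was 36.87% with DESeq2 size factors (2009 higher, 3440 lower) and 11.85% with total counts as the only scaling (1098 higher, 8165 lower), the latter chosen after seeing the data. Across all genes the median log2 fold change was -5.61 with TMM, -4.32 with DESeq2 size factors and -6.25 with total counts, and for 2766 genes with over 3 reads in the library labelled Th1 the other scalings moved values by 1.52 and -1.50. This test compares 1 library with 3 and has no replicate check of the single library, whose spread is assumed to equal that of the macrophage libraries.

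The genes named here as higher or lower kept their direction under all 3 scalings, but not all stayed past 4-fold. With total counts Ccl4 (0.89), Ccl2 (1.23), C1qb (1.80), Fcgr1 (1.87) and C1qc (1.995) had log2 fold changes under that limit, and with DESeq2 size factors so did S100a8 (-1.92), S100a9 (-1.75) and Retnlg (-1.56). On the TMM scale, higher in the library labelled Th1 were the chemokines Ccl7 (log2 fold change 9.77), Ccl5 (5.07), Ccl2 (2.72) and Ccl4 (2.38), all with an adjusted p of 2.25e-18 or less by edgeR. Macrophage markers Ms4a7 (7.23), Cd14 (4.27), Adgre1 (3.95), C1qc (3.49), Fcgr1 (3.36) and C1qb (3.29) were higher too, as were the cytokine genes Spp1 (9.31) and Mif (4.06), the receptor Cxcr4 (4.02) and Ly6c1 (6.25), with edgeR adjusted p of 2.27e-17 or less. These are the higher members of lists that were mixed or mostly lower. By edgeR, 6 macrophage and monocyte markers were called higher and 6 lower, 5 chemokines higher and 9 lower, 4 cytokines and growth factors higher and 7 lower, and 1 chemokine receptor higher and 6 lower. Among the lower members were C1qa, the partner of C1qb and C1qc, with 38 reads and a log2 fold change of -2.38 (-0.87 with DESeq2 size factors), Cd68 with 6 reads, Ccl3 with 3 reads, and Ccl12 and Il1b with 1 read each. Granulocyte transcripts were lower, at log2 fold changes of -8.51 for Lcn2, -3.44 for S100a8, -3.26 for S100a9 and -3.08 for Retnlg, and 11 of 14 neutrophil markers passed in that direction. Among the 10 most extreme genes in that direction were Ly6c2, at least 986-fold lower, Plac8, at least 585-fold lower, Ifitm6, at least 314-fold lower, and Wfdc21, at least 304-fold lower. The others were Ly6a2, Pglyrp1, Rac2, Fxyd5, Cxcl2 and Ly6g, at least 131-fold lower for the last, each without a read in the library labelled Th1, bounded at 3 reads there and given as the smallest bound of the 3 scalings. These bounds cover counting error only, not transcripts lost before sequencing. The library labelled Th1 had 2134 genes at 10 reads or more, against between 11005 and 11079 per macrophage library. Ly6c1, Ly6c2, Ly6a2 and Ly6g are close paralogs, between which reads may be split.

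The 10 genes with the largest fold in the other direction were Ppic, Eps8l2, Nr2f1, Mkrn3, Tnfrsf25, Rhox5, Rarres2, Slc7a3, Cldn4 and Lpar1. Ppic, a cyclophilin gene (chromosome 18, 53406341 to 53418007), had 5484 reads and 1485 TPM there and no read in any macrophage library, at least 42058-fold higher as the smallest bound of the 3 scalings, with the macrophage side at 3 reads over the group. Nr2f1, a nuclear receptor of neural development, had 1978 reads, and Rhox5, an X-linked homeobox gene of germ and placental lineages, had 1151 reads, and both were without a read in the macrophage libraries. Cldn4, a tight junction gene of epithelia, had 554 reads. Of the fixed lists in the library labelled Th1, cell cycle genes had 4 members higher and 18 lower, interferon response genes 4 higher and 19 lower, and antigen presentation genes 3 higher and 10 lower, by edgeR. Of all 11447 genes tested 6245 were called lower, and 15 of 23 cell cycle genes and 10 of 25 interferon response genes had no value there. The summed TPM of these lists ran the other way, at 1102 against 206 for cell cycle, 828 against 553 for interferon response and 8746 against 8199 for antigen presentation genes. Cytotoxic effectors had 1 member higher, Tnfsf10 with 42.7 reads, and 6 lower, and none of the other 14 members exceeded 3 reads except Lamp1 with 17 reads.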

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

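Tests chosen only after the results were seen were the mean-level limit, the removal of macrophage-enriched genes, the 3 cameraPR settings and total-count scaling. In the authors' deposited table, 69 genes passed an adjusted p of 0.01 (49 higher, 20 lower) in place of 106. 72 passed with a 2-fold limit, 97 at a mean of at least 50 normalized counts, and 96 without macrophage-enriched genes. The 96 are the 106 without the 10 enriched genes called higher, so this count is no check on the remaining calls. Macrophage-associated genes such as Gpnmb and Mmp12 stayed among them. Of 32 gene lists 14 passed, against 5 at a correlation of 0.05, 9 with log2 fold changes and 10 with ranks, by limma cameraPR, and the cause was not tested. Over these settings 76 list results kept their side of the threshold, 19 lost a call and 1 gained one, the Th1 list (adjusted p from 0.00405 with fold changes to 0.149 at a correlation of 0.05). Fa2h gained a call at the mean-level limit.

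For the library labelled Th1, DESeq2's Wald test called 4417 genes (43.67% higher) against 7812, and the cause was not tested. Without 1 macrophage library each, edgeR called between 7778 and 7790 genes, 8274 without a filter, 6822 at 8-fold and 8285 at 2-fold. List members at 1 TPM or more numbered 191 with deposited and with rescaled values. The rescaling factors lay between 0.9975 and 1.003, so this count could hardly change. In the library labelled Th1, 56.84% of genes with a value had 3 reads or fewer, and 83 of 568 genes at 100 TPM or more in the macrophage libraries had no read. The cause was not tested on these genes, and low RNA input is taken up below with proteasome genes.

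No paired analysis was possible because the OPC table holds no value per library and the immune groups share only replicate number 1. For the same reason leaving out OPC libraries, other scalings, tests, filters and pseudocounts, an estimated correlation, fry and other splits of the OPC libraries were not run.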

Other observations

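All tests of explanations here were chosen only after the results were seen. The authors' deposited table lists neuronal transcripts at high means, 31420 normalized counts for Stmn2 and 13070 for Rbfox3, beside 2251 for Pdgfra. With Tubb3 at 122300 and Nefl at 61470 normalized counts as well, it is open whether the content or annotation of that table is that of purified OPCs, which bears on every value taken from it. Its mean for C1qa is 1722 normalized counts, against 64.8 for C1qb and 58.1 for C1qc, which encode partner chains of the same complement protein. Of 19333 genes in the authors' deposited table, 133 had an SE over 3 times that of genes of similar level, and 16 of 23 cell cycle genes were among them (Fisher exact p = 2.3e-30, two-sided). The Fisher tests in this paragraph take genes as independent, so genes that vary together across the same libraries can make their p too small. Of the 133 genes 124 pointed higher, all 16 cell cycle genes included. The median SE ratio was 1.545 for genes called higher against 1.11 for genes called lower. Genes were matched on overall mean only, so a large fold that leaves few wild-type counts can also raise the ratio. Ccl4, for example, had 0.342 implied normalized counts in wild type. These medians therefore do not tell whether spread between libraries bears more on the increases than on the decreases. Among genes enriched in the macrophage libraries, 10 of 488 were called higher, against 62 of 14133 others (Fisher exact p = 0.000131, two-sided), and the 10 include Ccl4, Lyz2, Cd68, Lgals3 and Cybb. Mmp12 and Gpnmb count among the others, since the macrophage libraries hold little of them. In the macrophage libraries Il1b stood at 404 ± 3.21 TPM and Osm at 51.0 TPM on average.

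Phagocyte genes were higher together with Ccl4 in the Apc-deleted cultures. More resident microglia would raise microglia genes by as much as Fcer1g (1.49), but their median was 0.008 (SD 0.40 over 10 genes) in values of the authors' deposited table. Granulocytes would raise neutrophil genes, whose median was -0.18 (SD 0.373 over 11 genes) in values of the authors' deposited table. Uneven phagocyte numbers between libraries remain open, since the SE ratio had a median of 1.76 for the 10 genes against 1.515 for the other 62 (permutation test, p = 0.2), while single genes reached 7.07 (Lyz2), 4.64 (Lgals3) and 3.12 (Ccl4), and outside the 10 genes 7.88 (Gpnmb) and 4.03 (Mmp12). For Ccl4, with 0.342 implied normalized counts in wild type, few counts can also raise that ratio. The other 62 genes include the macrophage-associated Gpnmb and Mmp12, so the permutation test does not set phagocyte genes cleanly apart from the rest. Expression by OPCs themselves, and a changed state of phagocytes already present, with Csf1r and Cx3cr1 near 0, were not tested and stay open as effects of the genotype.

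Macrophage transcripts, with Lck the only T cell marker over 3 reads, were present in the library labelled Th1, despite its CD4 gate. They do not describe the whole library, since some macrophage markers were higher there and others lower. Its largest increases included Ppic, Nr2f1 and Rhox5, without a read in the macrophage libraries, and no explanation was tested on those genes. Carry-over of reads from the macrophage libraries would keep their proportions, but 5 of 13 neutrophil genes (38.46%; Lcn2, Mmp8, Mmp9, Elane and Ly6g) had over 10 times fewer reads than 1 common share of 0.664% predicts, and Ltf (16.1%) and Cxcr2 (13.1%) lay above it, although S100a8, S100a9, Retnlg and Ngp had between 0.427% and 0.555%. This argues against reads carried over after library construction, not against RNA or cells carried over earlier, and it replaced, after values per gene had been seen, an undecided test that found 4 of the 50 most abundant macrophage genes at 3 reads or fewer. Macrophage-type cells behind the library stay open, since the comparison of 12 of 17 macrophage with 1 of 13 T cell genes over 3 reads (Fisher exact p = 0.00078, two-sided) only restates the pattern. Low RNA input may also have removed genes, since 15 of 37 proteasome genes (40.54%, exact 95% interval 24.75% to 57.9%) had 3 reads or fewer, but 22 of 37 proteasome genes against 1 of 13 T cell genes exceeded 3 reads, a comparison that uses the count that prompted it and takes no account of each gene's level, and no biological explanation was tested.

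The macrophage libraries lay close to one another. Their biological coefficient of variation was 0.0222 over 10685 genes, which is consistent with 3 libraries from 1 RNA pool. Between library pairs the chi-square per degree of freedom was 2.53, 1.92 and 1.29, so counting error alone does not account for every difference. No source used here says how many animals were sorted, and no biological explanation was tested.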
